A study of Saccharolobus islandicus with 4 samples.

How the data were processed

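RNA was measured in 4 cultures of the thermophilic archaeon Saccharolobus islandicus, 1 library per group. Per the labels' protocols, the genetic host E233S1 (E233S in the sample titles), a derivative of strain REY15A referred to here as the wild type, and a strain lacking the gene cdc6-2 were grown at 78 °C to an early exponential phase with an A600 of ca. 0.20. NQO, the abbreviation used in the labels and in this field for a quinoline oxide that forms bulky adducts on DNA, was then added to 2 µM, and cells were collected after 6 h together with cultures that received no drug. Per the labels' protocols, ribosomal RNA was removed from 3 µg of total RNA, random-primed libraries with dUTP in the second strand were made with the NEBNext Ultra kit, and paired-end reads were generated on an Illumina HiSeq. The submitters' processing notes name CASAVA, Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq. The genome build, the annotation and the strand setting of the counting are not given in the sources used here, so counts of overlapping or antisense genes, and of small RNAs that lie within other genes, are uncertain.

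The authors deposited a table of read counts per gene for the 4 libraries, which holds raw whole numbers and was the input of every comparison. It lists 2674 genes, 2644 with a SiRe locus tag and 30 small RNAs, 13 of which had no count in any library. The authors also deposited FPKM values, which divide the counts by gene length and depth. A smaller FPKM table of 1182 genes held the same FPKM values within a relative difference of 7.16e-10 and was not used further. For each comparison the authors deposited a list of changed genes with a signal per library, which is the count scaled by the authors, a log2 fold change and an adjusted p-value. The smallest absolute log2 fold change in these deposited lists was 1.00 and the largest adjusted p-value 0.00486. With 1 library per group such p-values rest on assumptions about the spread between cultures, and their values were not used for any statement here. They enter only through which genes the deposited lists hold, since these lists served as an alternative setting and for descriptions. The deposited lists were the only source of gene descriptions. They give 1 word, often cut off, for 989 genes, and 350 of these read hypothetical. A reference table of another strain of the species, assembly M.16.4, matched 0 of the locus tags and was not used.

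Total counts were 2257991 in the untreated wild type, 3163874 in the NQO-treated wild type, 2866565 in the untreated mutant and 3102689 in the NQO-treated mutant. Library sizes were scaled with TMM factors from edgeR 4.0.16 under R 4.3.3, calculated over the 4 libraries, at 1.06, 0.838, 1.07 and 1.05 in the same order. Log2 ratios are differences of log2 CPM, the count scaled to the TMM library size, with a prior count of 2. A fold is the ratio of the scaled counts without a prior count, and it carries an exact 95% Clopper-Pearson interval of the share of the reads that fell in the first library. These intervals cover counting error only. Reads were amplified by PCR and are not independent molecules, and with 1 culture per group the spread between cultures is not known. In the plots, a library with 0 counts of a gene would be marked at a floor of 3 counts, and this floor entered no fold. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

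Each comparison set 1 library against 1, with no residual degrees of freedom, so a fixed size rule took the place of a test. A model of strain and NQO effects shared across all 4 libraries, which assumes equal responses in both strains, was not fitted. A gene was called higher or lower when it had at least 10 counts in 1 of the 2 libraries, differed at least 2-fold in log2 CPM and had a counting interval that excluded equality. The 4 comparisons were NQO against no drug in each strain, and mutant against wild type without and with NQO. A difference between the NQO responses of the strains was called when the wild type log2 ratio minus that of the mutant was at least 1 in size, with a normal 95% counting interval from the 4 counts that excluded 0. Such calls describe these libraries, not the conditions. The groups, the size rule, the alternative settings, the rule for named genes and 29 gene lists were set before the data were examined. The rule named, per comparison and direction, the 12 described genes with the largest log2 ratio among those with at least 100 counts in the library where they were higher, up to 2 genes with no description or described as hypothetical, the initiator genes, and the members of the gene lists (of lists with more than 10 measured members, the 4 that moved most). Genes named outside this rule are said to have been chosen after their values were seen.

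List members were found by words in the deposited descriptions, by locus tags, or both, and 8 of the 29 lists found no member. The tags of the Ups, Ced, Dpo2, Tfb3, cell division, chromatin and initiator genes, SiRe_1231 for cdc6-2 included, were recalled from earlier work on this strain and not checked against an annotation, as none was available. The assignment of SiRe_0002 and SiRe_1230 to the initiators is uncertain. Those of Ups, Ced, Dpo2 and Tfb3 are known in part through the study itself, so their direction is not independent evidence. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 10 bins. Random lists held scattered genes, while neighbouring genes tended to move together, so this rank overstates how unusual a list of neighbours is, and it is not given for the Ups, Ced, Dpo2, cell division, purine and recombination lists, which hold neighbours. The CRISPR, DNA, ribosome and translation, and ABC and peptide transport lists also hold some neighbours, so the ranks given for them carry the same limit. Lists made from descriptions were compared with described genes only, since the authors described only genes that they had listed as changed, and lists made from tags with every gene past the count filter. Another 8 lists were made from the descriptions after the data had been seen.

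The size rule was tested on simulated counts for the 2674 genes. For the wild type NQO comparison with counting noise alone, 46 of 50 genes set to 2.5-fold and 50 of 50 set to 4-fold were called, and 6 of 2233 unchanged genes were. With an assumed coefficient of variation between cultures of 0.2, 68 of 2239 unchanged genes were called, and with 0.4, 512 of 2242. Alternatives were scaling by total counts, by DESeq2 1.42.0 size factors and by totals without the 20 most abundant genes, no count filter, a minimum of 100 counts, a prior count of 0.5, a 3-fold rule, an interval wholly beyond 2-fold, the deposited FPKM on a log2(FPKM + 1) scale, and the authors' lists. Relative to TMM, total counts moved every log2 ratio by -0.33 in the wild type NQO comparison and by 0.33 between the NQO-treated strains, and totals without the 20 most abundant genes by -0.19 and 0.23, while all other shifts lay between -0.03 and 0.02. A search for promoter motifs needed a genome sequence and was not run.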

Results

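Transcripts were counted in 4 libraries of Saccharolobus islandicus, an archaeon of hot acidic springs, with 1 culture each of the wild type host and of a cdc6-2 deletion mutant, without drug or 6 h after addition of 2 µM NQO. The comparisons ask, as the series' title puts it, how Cdc6-2 takes part in the response to DNA damage. Cdc6-2, also called Orc1-2, belongs to the Orc1/Cdc6 family of archaeal replication initiators. Total counts lay between 2257991 and 3163874 per library. With 1 library per group there was no replicate check of any difference, and the ranges in parentheses after each fold are 95% counting intervals of a pair of libraries. At these depths, 100 counts in 1 library could be told from at most 73 in another of equal size, and 10 counts from at most 2.

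The deleted gene followed the labels. SiRe_1231, taken as the cdc6-2 locus, had 247 counts in the untreated wild type, 2110 in the NQO-treated wild type, 25 in the untreated mutant and 39 in the NQO-treated mutant. It was 12.7-fold lower in the mutant than in the wild type without NQO (8.42 to 20.0) and 66.8-fold lower with NQO (48.7 to 94.2). In the wild type it was itself 7.68-fold higher with NQO (6.73 to 8.80). The reads left in the mutant were 7.86% of the wild type level without NQO (95% counting interval 4.99 to 11.9) and 1.5% with NQO (1.1 to 2.1).

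In the wild type, genes for pili, DNA transfer and a DNA polymerase were far more abundant with NQO, and genes for cell division and chromatin far less. The 5 genes of the Ups cluster, which makes type IV pili for cell aggregation after DNA damage, were all higher, with a median log2 ratio of 6.92. SiRe_1881 of this cluster went from 712 to 182577 counts, 231-fold higher (214 to 249), and took 5.77% of all counts of the treated library against 0.0315% of the untreated one. SiRe_1879 was 148-fold higher (125 to 177), SiRe_1882 126-fold (93.2 to 175), SiRe_1880 76.2-fold (57.3 to 103) and SiRe_1878 57.0-fold (49.0 to 66.7). Of the Ced genes, which import DNA from other cells, 3 of 3 were higher: SiRe_1857, described as AAA, 90.4-fold (77.5 to 106), SiRe_1316 54.7-fold (49.3 to 60.9) and SiRe_1317 46.5-fold (43.2 to 50). Of the 4 genes of the Dpo2 cluster, named for a DNA polymerase of the B family, 3 had enough counts, and all 3 were higher. They were SiRe_0615 at 33.5-fold (27.8 to 40.8), SiRe_0614 at 24.9-fold (15.9 to 41.0) and SiRe_0616 at 15.7-fold (10.8 to 23.7). SiRe_1717, the gene of the transcription factor B paralogue Tfb3, had 17 counts without and 2313 with NQO, 122-fold higher (76.3 to 210). These lists are known in part through the study itself, so their direction is not independent evidence.

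The 6 cell division genes encode CdvA, proteins of the ESCRT-III family and the ATPase Vps4, which constrict and cut the cell. Of these, 5 were lower with NQO, and 6 were with scaling by total counts. SiRe_1550 was 108-fold lower (98.3 to 119) and SiRe_1200 76.3-fold lower (70.8 to 82.3), its share of the counts being 2.13% without and 0.0222% with NQO. SiRe_1388 was 6.54-fold lower (4.56 to 9.65), SiRe_1175 4.4-fold (3.94 to 4.93) and SiRe_1174 3.04-fold (2.56 to 3.62), whereas SiRe_1173 lay at 1.73-fold (1.55 to 1.92), inside the size rule. SiRe_1172, next to these in number and described as hypothetical, was 86.6-fold lower (63.4 to 121). The list's median log2 ratio was -2.39. The chromatin proteins, which bend and compact DNA, were lower in 3 of 3 genes (median -3.15, as low in 2 of 10000 random lists). SiRe_1111 (Cren7) was 38.2-fold lower (31.7 to 46.5), SiRe_2648 11.3-fold (4.90 to 32.0) and SiRe_0668 2.49-fold (1.64 to 3.84). The last pair were taken to be near-identical copies of the Sul7d gene, between which reads may be divided wrongly.

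Other fixed groups in the wild type split or held a few genes. Lists made from descriptions hold only genes that the authors had listed as changed in at least 1 comparison. Their counts, here and below, can leave out unchanged genes of the same family and are not response rates of that family. Enzymes of deoxynucleotide supply were lower in 3 of 3 cases, with a median log2 ratio of -1.80 that lay inside the central 95% of random lists of described genes (as low in 394 of 10000), deoxycytidine SiRe_1817 7.83-fold (7.07 to 8.68), thymidylate SiRe_1676 3.50-fold (2.98 to 4.12) and deoxycytidine SiRe_2287 3.26-fold (2.75 to 3.88). The archaellum filament gene, flagellin SiRe_0124, was 95.9-fold lower (71.3 to 132). Among 4 genes taken as initiators, 2 of them (SiRe_0002 and SiRe_1230) with an uncertain assignment, SiRe_1231 was higher and SiRe_1740 lower, 5.64-fold (4.68 to 6.84), while SiRe_1230 and SiRe_0002 were not past the rule. SiRe_0002 was at 2.00-fold (1.63 to 2.44) and counted as lower under the other 3 scalings. In the repair lists, the nuclease gene NurA SiRe_0061 was 3.16-fold higher (2.57 to 3.91) and the Holliday gene SiRe_0930 7.98-fold lower (5.14 to 12.9). The apurinic endonuclease genes SiRe_1180 and SiRe_1884 were 3.07-fold (2.32 to 4.10) and 2.77-fold higher (2.17 to 3.55), with XPD SiRe_1685 at 1.37-fold (1.14 to 1.64), not past the rule. Iron and oxygen stress genes were higher in 4 of 9 cases, as ferritin SiRe_0453 at 15.4-fold (13.4 to 17.7) and rubrerythrin SiRe_2563 at 5.03-fold (4.95 to 5.11). With total counts or without the 20 most abundant genes, 3 were higher and 1 lower, and with DESeq2 factors 4 and 1.

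Genes listed as respiratory, here and below by words such as cytochrome or Rieske, went both ways in the wild type, 2 higher and 4 lower of 10. The 2 higher ones were listed by the word Rieske alone, which does not show a respiratory role. The neighbours SiRe_2267 to SiRe_2270 were lower, cytochrome-c SiRe_2267 by 3.25-fold (3.21 to 3.29), while the Rieske genes SiRe_0454 and SiRe_2437 were 26.3-fold (10 to 98.2) and 13.2-fold higher (12 to 14.6). CRISPR genes, of the antiviral system, were higher in 4 and lower in 2 of 15 cases, and lower in 5 under total counts or without the 20 most abundant genes. SiRe_0761 was 59.5-fold (32.2 to 125) and SiRe_1994 14.2-fold higher (11.9 to 17.1). Transposase genes were higher in 2 and lower in 5 of 7 cases, the 5 being of the IS200/IS605 family. The ratio of FPKM to CPM was the same for these 5, so their annotated lengths are equal. If they are copies of 1 element, reads may be divided wrongly between them, and they are not separate cases. Genes listed as toxin-antitoxin, here and below by words such as VapB, VapC or AbrB, were higher in 2 and lower in 2 of 10. Of these, 4 were lower under total counts and 3 without the 20 most abundant genes. The word AbrB alone does not show a toxin-antitoxin role. The VapC gene SiRe_0744 was 3.78-fold higher (2.59 to 5.67) and the AbrB gene SiRe_1949 7.79-fold lower (6.90 to 8.82). The helicase gene MCM SiRe_1228 was 2.21-fold higher (1.87 to 2.61), as was the thermosome SiRe_1214 (2.15 to 2.29) of 2 chaperone genes. Both fell under 2-fold with total counts or without the 20 most abundant genes. The ArsR regulators SiRe_1806 and SiRe_2512 were 9.12-fold (6.55 to 13) and 2.37-fold lower (2.19 to 2.57). ParB SiRe_1885 and the proteasome gene SiRe_1237 were not past the rule, although ParB counted as lower under total counts and without the 20 most abundant genes.

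Outside the lists, the described genes that were highest with NQO included SiRe_1957, described as fagellar, at 149-fold (136 to 164). The transport gene SiRe_0137 was also 149-fold higher (117 to 192), the zinc gene SiRe_0670 63.3-fold (51.4 to 78.8), the glycoside gene SiRe_0936 47.4-fold (38.0 to 59.9) and the Peptidase SiRe_2664 28.3-fold (26.1 to 30.7). Among those lowest were the CopG regulator SiRe_1577 at 39.4-fold (30.9 to 50.8), the XRE regulator SiRe_1891 at 19.5-fold (14.2 to 27.4) and SiRe_1948, described as transcriptional, at 17.4-fold (16.6 to 18.3). In total, 381 genes were higher and 353 lower of 2491 tested, and 68 and 33 of these differed at least 8-fold. The higher share of the calls, 51.9%, depended on the scaling: it was 29.7% with total counts, 37.8% without the 20 most abundant genes, 37.0% with FPKM and 49.1% with DESeq2 factors.

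**Figure D1:**
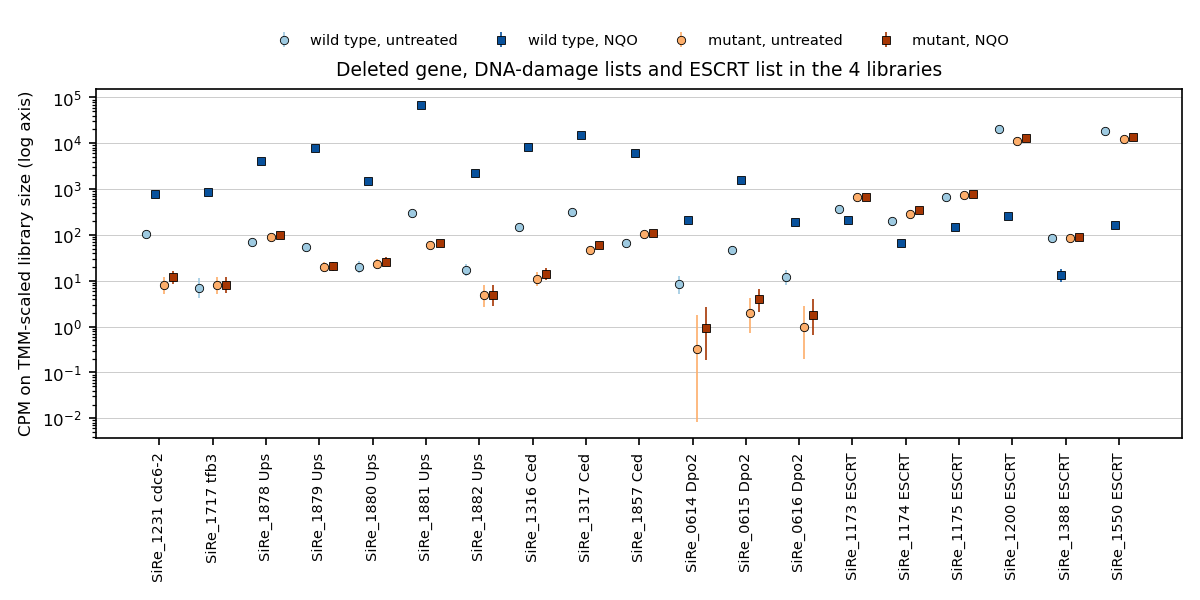
CPM (log axis) in each of the 4 libraries for SiRe_1231, SiRe_1717 and the Ups, Ced, Dpo2 and cell division genes, with 95% exact Poisson counting bars. SiRe_1881 had 712 counts in the untreated and 182577 in the NQO-treated wild type, against 183 and 220 in the mutant.

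In the mutant, none of these damage groups was past the size rule with NQO. This held for 0 of 5 Ups genes, 0 of 3 Ced genes, the 1 Dpo2 gene with enough counts, SiRe_1717 and 0 of 6 cell division genes. SiRe_1881 had 183 counts without and 220 with NQO, 1.13-fold (0.923 to 1.38), and SiRe_1717 had 25 and 27, 1.01-fold (0.566 to 1.82). SiRe_1316 was at 1.30-fold (0.817 to 2.08), SiRe_0615 at 2.03-fold from 6 and 13 counts (0.721 to 6.52) and SiRe_1550 at 1.11-fold (1.10 to 1.13). Chromatin genes were lower in 2 of 3 cases (median log2 ratio -1.15, as low in 11 of 10000 random lists), SiRe_1111 by 2.23-fold (2.08 to 2.38) and SiRe_2648 by 2.55-fold (1.54 to 4.34).

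The genes past the rule in the mutant with NQO were few, 24 higher and 44 lower of 2467 tested, or 2.76%. In the simulation of this comparison, an assumed coefficient of variation between cultures of 0.2 led to calls for 2.82% of 2269 unchanged genes. A spread of that size alone would give a similar share, so these calls need not reflect NQO. The highest were SiRe_0655, hypothetical, at 47.0-fold (30.3 to 77.3), the zinc gene SiRe_0630 at 9.60-fold (7.43 to 12.6), its hypothetical neighbour SiRe_0629 at 9.25-fold (5.33 to 17.4) and the cupin gene SiRe_0621 at 5.05-fold (3.58 to 7.31). The 4Fe-4S gene SiRe_0654 was 4.75-fold (3.72 to 6.13), the radical gene SiRe_1524 3.53-fold (3.08 to 4.05) and SiRe_0300, described as major, 3.43-fold higher (3.20 to 3.68). Among the lowest, beta-lactamase SiRe_0574 was 4.80-fold lower (4.31 to 5.37), SiRe_0955, hypothetical, 4.50-fold (4.13 to 4.90), the AbrB genes SiRe_1949 and SiRe_1494 3.53-fold (3.26 to 3.84) and 2.49-fold (2.33 to 2.67), and SiRe_1948 2.35-fold (2.28 to 2.43). CRISPR genes were lower in 4 of 15 cases, the neighbours SiRe_0760 to SiRe_0763, between 2.29-fold and 2.52-fold. Transposases were higher in 2 of 4, IS110 SiRe_0856 at 2.08-fold (1.69 to 2.57) and IS200/IS605 SiRe_1063 at 3.00-fold from 5 and 16 counts (1.05 to 10.5). Of the 10 genes listed as toxin-antitoxin, 2 were lower, both described only as AbrB, which does not show a toxin-antitoxin role. No member was past the rule among 9 oxidative stress, 10 respiratory, 4 initiator, 3 deoxynucleotide, 3 excision repair, 2 recombination, 2 chaperone and 2 regulator genes, nor was MCM, flagellin, ParB or the proteasome gene.

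The difference between the strains' NQO responses was measured from all 4 counts per gene. It was past the rule in 5 of 5 Ups, 3 of 3 Ced and 3 of 3 Dpo2 genes, all with the larger log2 ratio in the wild type. Only 1 of these Dpo2 genes, SiRe_0615, had enough counts in the mutant comparison. SiRe_0614 had 1 and 3 counts in the mutant and SiRe_0616 had 3 and 6, so their mutant ratios were hardly measured. Their calls depend on the prior count and the normal interval. For SiRe_1881 the wild type log2 ratio exceeded that of the mutant by 7.67 (7.37 to 7.98), for SiRe_1717 by 6.78 (5.75 to 7.81) and for SiRe_0615 by 4.23 (2.85 to 5.61). In the other direction, 5 of 6 cell division, 3 of 3 chromatin and 3 of 3 deoxynucleotide genes had the lower ratio in the wild type, with differences of -6.90 for SiRe_1550 (-7.04 to -6.76) and -4.08 for SiRe_1111 (-4.37 to -3.79). SiRe_0300 had near equal ratios, 1.74 in the wild type and 1.78 in the mutant. Of 2510 genes, 326 had the higher log2 ratio in the wild type and 305 the lower one, a balance that depended on the scaling: with total counts these were 209 and 507. Of the 381 genes higher in the wild type, 356 had enough counts in the mutant, and 344 of these lay within 2-fold there, with a median log2 ratio of 0.15 against 1.52 for all 381 in the wild type. Of the 353 lower, 349 had enough counts and 321 lay within 2-fold, with a median of -0.18 against -1.48. Past the rule in both strains, 5 genes were higher and 20 lower in both. In opposite directions, 8 were lower and 4 higher in the wild type. Across genes, which are not independent replicates, the ratios of the strains had a Pearson correlation of 0.20 and a Spearman correlation of 0.28.

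**Figure D2:**
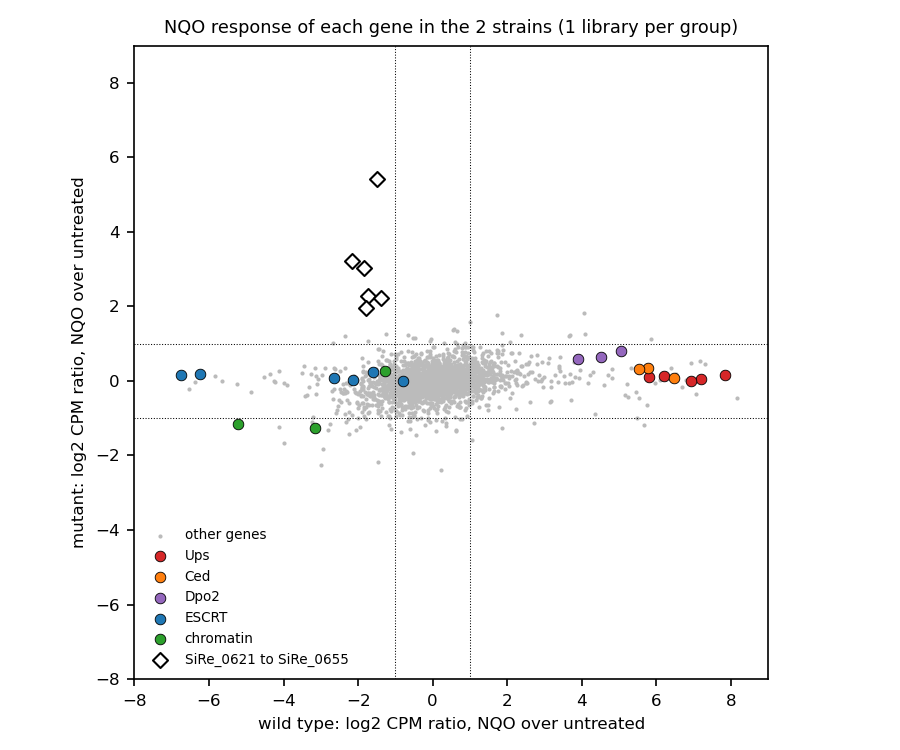
Log2 ratio of CPM with NQO over without, in the wild type (x axis) against the mutant (y axis), 1 point per gene with at least 10 counts in 1 of the 4 libraries and dotted lines at 2-fold. Across the genes past the count filter of each comparison, 2491 in the wild type and 2467 in the mutant, the standard deviation was 1.36 and 0.42.

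Without NQO, 4 runs of at least 4 neighbouring genes were higher in the mutant and 6 were lower, and several of the damage-related genes were already lower. The CRISPR-associated genes SiRe_0760 and SiRe_0761 were 43.4-fold (29.5 to 66.7) and 46.7-fold higher (25.2 to 97.8), from 26 and 10 counts in the wild type to 1453 and 601. This comparison shares the untreated wild type library with the wild type NQO response and the untreated mutant library with the mutant NQO response. Its differences are therefore not observations separate from those responses. The 10 counts of SiRe_0761 are also the base of its 59.5-fold rise with NQO in the wild type. Between the untreated strains, SiRe_0762, SiRe_0763 and SiRe_0764 were 17.9-fold (4.67 to 152), 17.7-fold (8.78 to 41.5) and 5.6-fold higher (4.23 to 7.55). Of the 15 CRISPR genes 5 were higher and 7 lower, or 6 lower under total counts and without the 20 most abundant genes. The lower ones included SiRe_0765 to SiRe_0767, SiRe_0771 and SiRe_0772 of the same stretch, chosen after their values were seen, and the list's median log2 ratio of 0.12 was as high in 4946 of 10000 random lists. The 11 consecutively numbered genes SiRe_2533 to SiRe_2543 were all higher. SiRe_2537, described as cellobiose, was 11.5-fold higher (11.2 to 11.8), from 5911 to 87797 counts, and held 3.06% of the counts in the mutant against 0.262% in the wild type. In the same stretch the oligopeptide/dipeptide genes SiRe_2534 and SiRe_2535 were 9.0-fold (6.94 to 11.9) and 5.93-fold higher (5.16 to 6.83). The mandelate gene SiRe_0431 and the D-galactarate gene SiRe_0430 were 14.3-fold (9.80 to 21.8) and 7.48-fold higher (5.53 to 10.3).

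Lower in the untreated mutant were the genes of the Dpo2 list in 3 of 3 cases, of Ups in 3 of 5 and of Ced in 2 of 3. SiRe_0615 went from 113 counts in the wild type to 6, 24.3-fold lower (10.8 to 67.5), SiRe_1316 was 13.5-fold (9.50 to 19.8), SiRe_1317 6.80-fold (5.69 to 8.18) and SiRe_1881 5.01-fold lower (4.25 to 5.93). SiRe_1878, SiRe_1880 and SiRe_1857 were at 1.28-fold (1.06 to 1.56), 1.18-fold (0.809 to 1.74) and 1.54-fold (1.27 to 1.88) in the other direction, and SiRe_1717 at 1.14-fold (0.593 to 2.25). List medians were -3.14 for Dpo2, -1.41 for Ups and -2.75 for Ced. Other genes that were far lower included SiRe_0655 at 67.9-fold (43.7 to 112), SiRe_0629 at 26.7-fold (15.6 to 49.4), zinc SiRe_0630 at 17.4-fold (13.5 to 22.7) and cupin SiRe_0621 at 12.5-fold (9.01 to 17.9). In the untreated mutant SiRe_0655, SiRe_0629, SiRe_0630 and SiRe_0621 had 20, 14, 65 and 39 counts. Their rises with NQO in the mutant rest on the same counts. The 4Fe-4S gene SiRe_2630, with 24967 counts in the untreated wild type, was 3.60-fold lower (3.52 to 3.69) in the untreated mutant.

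None of the 6 cell division, 3 chromatin or 3 deoxynucleotide genes was past the rule between the untreated strains, nor was MCM, flagellin, ParB or either ArsR regulator. Transposases were lower in 5 of 6 cases, all of IS200/IS605, such as SiRe_0690 with 22 counts in the wild type and 2 in the mutant, 14.2-fold lower (3.48 to 124). IS110 SiRe_0856 was 2.74-fold higher (1.90 to 4.04), and the list's median of -2.01 was as low in 69 of 10000 random lists. If the 5 IS200/IS605 genes are copies that share reads, this rank overstates how unusual the list is. Excision repair genes were higher in 2 of 3, SiRe_1180 at 3.52-fold (2.69 to 4.67) and XPD SiRe_1685 at 2.92-fold (2.5 to 3.43). Oxidative stress genes were higher in 3 of 9, or 2 with DESeq2 factors, such as ferritin SiRe_0453 at 4.09-fold (3.53 to 4.75). Of 10 respiratory genes 3 were higher and 1 lower, with Rieske SiRe_0454 at 6.79-fold higher from 4 and 35 counts (2.43 to 26.3) and Rieske SiRe_2316 at 2.94-fold lower (2.64 to 3.28). Toxin-antitoxin genes were higher in 2 of 10, or 1 with DESeq2 factors, and lower in 3. Holliday SiRe_0930 was 2.87-fold lower (2.17 to 3.83) of 2 recombination genes, the proteasome gene SiRe_1237 2.24-fold lower (2.07 to 2.43), and prefoldin SiRe_1653 of 2 chaperone genes 2.19-fold higher (1.79 to 2.70). Of the 4 genes taken as initiators SiRe_1231 alone was past the rule. In all, 257 genes were higher and 226 lower of 2464 tested, or 19.6%. In the simulation of this comparison, an assumed coefficient of variation between cultures of 0.4 led to calls for 22.6% of unchanged genes. A spread of that size could give such a share too. In the mutant with NQO, the same assumed spread gave 24.1%, where 2.76% were called.

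**Figure D3:**
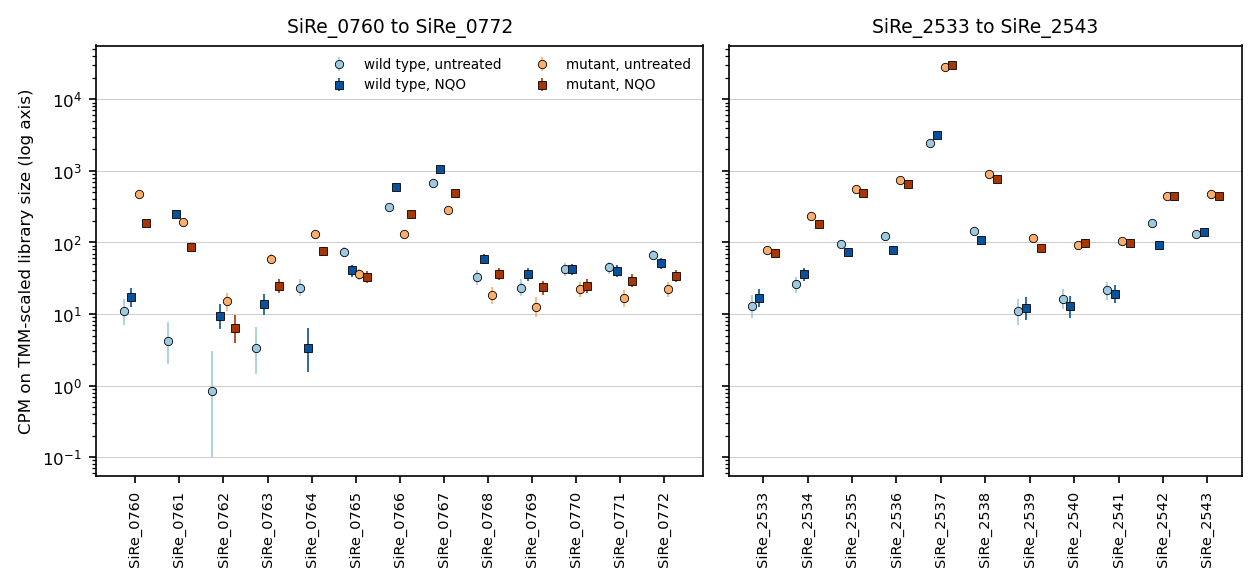
CPM (log axis) in each of the 4 libraries for the consecutively numbered genes SiRe_0760 to SiRe_0772 and SiRe_2533 to SiRe_2543, with 95% exact Poisson counting bars. SiRe_2537 had 5911 and 8531 counts in the wild type without and with NQO, and 87797 and 98540 in the mutant.

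With NQO, the mutant lacked the high counts of the damage groups and kept those of cell division. This comparison shares the NQO-treated wild type library with the wild type response, so its directions are not a second observation of that response. SiRe_1881 had 182577 counts in the wild type and 220 in the mutant, 1024-fold lower (898 to 1175), SiRe_1316 was 570-fold lower (429 to 776), SiRe_0615 400-fold (234 to 751) and SiRe_1717 106-fold (72.5 to 161). The 5 Ups genes were all lower, with a median log2 ratio of -8.54, as were 3 of 3 Ced genes (median -7.96) and 3 of 3 Dpo2 genes (median -7.01). SiRe_0670 had 6334 counts in the wild type and 2 in the mutant, 3910-fold lower (1082 to 32289), SiRe_0269, hypothetical, was 1163-fold (832 to 1679), SiRe_0137 773-fold (489 to 1304) and SiRe_1957 347-fold lower (308 to 393). The 6 cell division genes were all higher, with a median of 2.54, SiRe_1550 by 83.1-fold (75.7 to 91.4) and SiRe_1200 by 49.2-fold (45.7 to 53.1).

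Flagellin SiRe_0124 was 48.5-fold higher (36.0 to 67.0) in the treated mutant than in the treated wild type, CopG SiRe_1577 20.7-fold (16.2 to 26.8) and XRE SiRe_1891 14.0-fold (10.2 to 19.7). Deoxynucleotide genes were higher in 3 of 3 cases (median log2 ratio 1.92, as high in 157 of 10000 random lists), SiRe_1817 by 5.29-fold (4.77 to 5.87), and chromatin genes in 2 of 3, or 3 under total counts, with SiRe_1111 at 9.42-fold (7.77 to 11.5). SiRe_1740 and SiRe_0002, taken as initiator genes, the second with an uncertain assignment, were 8.60-fold (7.20 to 10.3) and 2.15-fold higher (1.78 to 2.60). The CRISPR genes SiRe_0764 and SiRe_0760 were 22.7-fold (11.8 to 50.2) and 10.8-fold higher (8.02 to 15.0), 3 of the 15 being higher and 4 lower. Under total counts these were 5 and 2, and without the 20 most abundant genes 4 and 3. SiRe_2537 was 9.36-fold higher (9.15 to 9.57).

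Ferritin SiRe_0453 and rubrerythrin SiRe_2563 were 3.55-fold (3.33 to 3.79) and 3.88-fold lower (3.83 to 3.93) among 9 oxidative stress genes, of which 2 were higher, or 3 under total counts, and 4 lower. Respiratory genes were higher in 3 and lower in 2 of 10, with 6 higher under total counts and 4 without the 20 most abundant genes. Cytochrome SiRe_2548 was 3.66-fold higher (3.51 to 3.82) and Rieske SiRe_2437 19.3-fold lower (17.5 to 21.4). Toxin-antitoxin genes were higher in 2 and lower in 3 of 10, or lower in 2 under total counts and without the 20 most abundant genes. Holliday SiRe_0930 was 3.56-fold (2.24 to 5.86), XPD SiRe_1685 2.27-fold (1.99 to 2.59), ParB SiRe_1885 2.33-fold (1.86 to 2.94) and ArsR SiRe_1806 12.7-fold higher (9.20 to 17.9). ArsR SiRe_2512 was past the rule under total counts, without the 20 most abundant genes and with FPKM (711 in the wild type, 1598 in the mutant). It was not with TMM or DESeq2 factors. Of 5 transposases SiRe_1859 was lower, 46.9-fold from 38 counts to 1 (7.93 to 1901), and MCM, the proteasome gene and both chaperone genes were not past the rule. In all, 284 genes were higher and 284 lower of 2499 tested, or 22.7%. An assumed coefficient of variation between cultures of 0.4 led to calls for 24.3% of unchanged genes in the simulation of this comparison. The higher share, 50%, was 72.6% with total counts, 66.5% without the 20 most abundant genes, 73.3% with FPKM and 51.8% with DESeq2 factors.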

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

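All tests in this part were chosen only after the results had been seen. Attention was drawn to 12 genes that were past the size rule in opposite directions with NQO in the strains, a difference that was not tested across cultures, since each group held 1. The value given for each is the wild type log2 ratio minus that of the mutant. Counts are in the order untreated wild type, NQO-treated wild type, untreated mutant, NQO-treated mutant. Lower in the wild type and higher in the mutant were SiRe_0655 (hypothetical) at -6.91, with 1054, 412, 20 and 1002 counts, the zinc gene SiRe_0630 at -5.38 (876, 217, 65 and 665), SiRe_0629 (hypothetical) at -4.88 (290, 88, 14 and 138) and SiRe_0631 (hypothetical) at -3.74 (165, 52, 33 and 143). The cupin gene SiRe_0621 followed at -4.01 (380, 126, 39 and 210), the 4Fe-4S gene SiRe_0654 at -3.61 (499, 210, 79 and 400), SiRe_0445, described as major, at -3.70 (49, 7, 9 and 22) and the IS200/IS605 gene SiRe_1063 at -2.52 (26, 11, 5 and 16).

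Higher in the wild type and lower in the mutant were the CRISPR-associated neighbours SiRe_0761 at 6.86 (10, 662, 601 and 280 counts), SiRe_0762 at 3.86 (2, 25, 46 and 21) and SiRe_0763 at 3.11 (8, 37, 182 and 80). For these neighbours the widest log2 gap set the untreated wild type library apart from the others. With 1 library per group, an unusual untreated wild type culture cannot be told apart from other causes of their wild type side. SiRe_0824, with no description, was at 2.66 (9, 23, 27 and 8). After Bonferroni correction over all genes, 7 of the 12 kept counting intervals that excluded equality in both strains, while SiRe_0445, SiRe_0762, SiRe_0763, SiRe_0824 and SiRe_1063 did not, so for these 5 counting error was not excluded at that level.

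The pattern weighed here is that of SiRe_0621, SiRe_0629 to SiRe_0631, SiRe_0654 and SiRe_0655, whose numbers lie close together. For these, counting error is argued against, since 6 of 6 had intervals that excluded equality in both strains after that correction. An unusual untreated mutant culture could account for the mutant side, and it cannot be told apart from an effect of the deletion on these genes: for 5 of the 6, the widest log2 gap set the untreated mutant library apart from the other 3, and that group held 1 culture. A strain-dependent response of these genes to NQO, which the design names, stays open and untested.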

How the results depend on the processing

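The comparison with the central 99% of the mutant pair was chosen only after the results had been seen; all other alternatives were fixed in advance. No paired analysis was possible within a comparison because each group held 1 library, and an NQO effect shared by both strains was not fitted. The promoter motif search was not run. Of 111 counts and correlations under the alternatives, 80 stayed within 1.5 times the main value. None of the 1155 values of named genes or 348 list medians changed direction in a call, but this carries no information on robustness. A called gene differed at least 2-fold, a log2 ratio of 1 in size, while the scalings of the counts moved log2 ratios by at most 0.33. Such shifts could not reverse a call, and the random lists set against list medians shift alike. Of the named genes 26 values moved past the rule and 13 came inside it.

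With total counts, 237 genes were higher and 561 lower with NQO in the wild type (381 and 353 with TMM), 507 were higher in the treated mutant than in the treated wild type (284), and the response was higher in the wild type for 209 genes and lower for 507 (326 and 305). With FPKM the last number was 503, and 532 genes were higher in the treated mutant than in the treated wild type. The scalings of the counts shift every log2 ratio of a comparison alike, by -0.33 and 0.33 for total counts in the comparisons that hold the NQO-treated wild type library. Before its pseudocount, FPKM divides by a depth per library and so also shifts every log2 ratio of a comparison alike. Its counts moved the same way as those with total counts. The pseudocount alters the shift for genes of low FPKM, and the FPKM setting required no counting interval. How much each of these contributed was not tested. The median of the excision repair list between the untreated strains was 1.56 with total counts against 1.54, the shift common to all genes; it lay at the edge of the central 95% of random lists, which were drawn anew for each scaling, so its side of that edge carries no information.

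Stricter rules leave fewer genes by construction. A 3-fold rule gave 184 higher and 159 lower in the wild type with NQO, 8 and 7 in the mutant (24 and 44 at 2-fold), 65 and 71 between the untreated strains (257 and 226), 114 and 144 between the treated strains (284 and 284), and 153 and 132 for the difference of responses. Intervals wholly beyond 2-fold gave 2.3e2 and 232, 8 and 16, 116 and 131, 165 higher between the treated strains, and 182 and 164 for the difference. At least 100 counts left 10 genes higher in the mutant with NQO, and the authors' deposited list held 9 higher and 28 lower there. Outside the central 99% of the mutant pair at the same expression, 162 genes were higher and 144 lower between the untreated strains. The correlation of the responses stayed between 0.19 and 0.21. Depth limited the rule for rare transcripts, where 10 counts needed at most 2 in the other library, a 5-fold difference.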

Other observations

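All tests in this part, and the gene groups they used, were chosen only after the results had been seen. Small RNAs, which the deposited table lists beside the genes, were higher with NQO in the wild type in 9 and lower in 2 of 16 measured cases. In the mutant 0 of 11 were past the size rule with NQO, and 1 was higher and 2 lower of 12 between the untreated strains. The NQO-treated mutant was lower than the NQO-treated wild type in 9 of 16. In the wild type sRNA00021 went from 1 to 856 counts, 770-fold higher (138 to 30446), sRNA00028 from 3 to 694, 208-fold (70.9 to 1011), sRNA00008 from 3 to 477, 143-fold (48.6 to 696), and sRNA00018 from 64 to 1905, 26.8-fold (20.9 to 34.9). The table holds no positions, so overlap of these with other genes was not examined.

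Of the 8 lists made later, that of purine synthesis words had 7 of 9 genes lower with NQO in the wild type (8 under the other 3 scalings), with a median log2 ratio of -1.88, against 0 of 9 in the mutant. Of the 7, 5 form 1 run of neighbours, SiRe_1376 to SiRe_1380. SiRe_1378 went from 894 to 187 counts, 5.32-fold lower (4.54 to 6.26), and SiRe_1376 was 3.72-fold lower (3.13 to 4.44). Genes described as recombination were higher in the wild type in 3 of 3 cases and in 0 of 3 in the mutant. SiRe_0062 was at 4.93-fold (3.66 to 6.76), SiRe_0063 at 5.31-fold (4.24 to 6.70) and SiRe_0064 at 6.12-fold (5.43 to 6.91), all neighbours and next in number to the NurA gene SiRe_0061. Genes described as DNA were higher in 6 of 6, but in 2 under total counts or without the 20 most abundant genes, and 823 of 10000 random lists had a median as high. This list includes SiRe_0614 and SiRe_0615 of the Dpo2 list, so it is not separate from that result.

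Genes described as major were higher with NQO in 3 and lower in 13 of 27 cases in the wild type, or lower in 18 under total counts; with TMM, to which all counts of random lists here refer, the median was as low in 501 of 10000. In the untreated mutant 12 of the 27 were lower than in the wild type, or 10 under total counts, and the median was as low in 23 of 10000 random lists. AsnC regulators were higher there in 4 of 5 cases (20 of 10000 as high). Genes described as transcriptional were lower with NQO in 4 of 6 in the wild type, or 6 under total counts (146 of 10000 as low). Ribosome and translation words gave 6 higher and 1 lower of 12, or 2 and 2 under total counts (735 of 10000 as high), and ABC and peptide transport words 9 and 9 of 33, or 5 and 11 (1771 of 10000 as high). Between the untreated strains the last list had 9 higher and 4 lower of 33, with a median as high in 4956 of 10000 random lists.

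Genes next to each other in number often moved together. In the wild type with NQO, 214 neighbouring pairs of called genes had the same direction and 58 opposite ones, where shuffled gene orders gave 98.5 pairs of the same direction on average and 135 at most in 10000. The same count was 11 in the mutant (0.936 and 7), 118 between the untreated strains (43.7 and 67) and 169 between the treated ones (59.0 and 85). The 11 genes SiRe_0119 to SiRe_0129, flagellin SiRe_0124 among them, were all lower with NQO in the wild type. The 8 genes SiRe_2307 to SiRe_2314 were all lower in the untreated mutant, SiRe_2313 by 5.91-fold (4.16 to 8.59).

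Reads on the deleted gene SiRe_1231 in the mutant libraries are the first pattern weighed here. Each mutant library was compared only with the wild type library of the same treatment. RNA of the untreated wild type, as the source of all these reads in the untreated mutant library, is argued against by 1 of 2077 genes. SiRe_0655 had 20 counts there against 1054 in the wild type, at most 3.45% of the wild type level. This is below the 4.99% that SiRe_1231 kept at least. RNA of the NQO-treated wild type, as the source of all these reads in the NQO mutant library, is argued against by 14 of 2112 genes. An example is SiRe_1881 at 0.0976% of the NQO-treated wild type level (at most 0.128%). Wild type RNA of the other treatment, or as the source of only a part of the reads, was not tested. A part of the gene left in the deletion strain cannot be told apart from other sources of these reads, 1.5% of the wild type level with NQO, because a table of counts per gene holds no read positions.

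The other pattern is that most genes past the rule with NQO in the wild type were not past it in the mutant. Lower sensitivity of the mutant libraries is argued against for 705 of the 734 genes called in the wild type, those with enough mutant counts. For only 3.55% of these did the mutant interval reach the wild type ratio, whose own counting error was not included. The other called genes could not be tested: of the 68 higher at least 8-fold, 52 had enough counts in the mutant. That NQO did not reach the treated mutant culture cannot be told apart from an effect of the deletion. Of 30 blocks of neighbouring genes called in both strains, 76.7% went the same way (57.7 to 90.1), but the genes of 1 pair of libraries can move together without NQO. An effect of the deletion on the response, which the design names, stays open and was not tested across cultures, since each group held 1.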
